A study of Mus musculus with 4 samples.

How the data were processed

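Nucleosome positions were mapped by MNase-seq, in which micrococcal nuclease digests the DNA between nucleosomes and the protected fragments are sequenced. The samples were livers of C57BL/6 mice aged 3 months (2 libraries) and 21 months (2 libraries), and group and replicate number were taken from the sample titles. Per the labels' protocols, nuclei from snap-frozen tissue were digested at a chosen enzyme amount, mononucleosome-sized fragments were selected, and libraries were sequenced on an Illumina instrument. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

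Per the submitters' processing notes, the reads were aligned with BWA to the mm9 build. The BWA version, the nucleosome caller and its settings are not given in the sources used here. The authors deposited 1 list of called nucleosomes per library. Every listed nucleosome was 140 bp wide. The height of each nucleosome is the signal (occupancy) at its summit as deposited by the authors, per the file headers. The fuzziness score and the p-value of each nucleosome were likewise deposited by the authors, per the file headers, and the p-values were not used here. Read numbers are not given in the sources used here, so the sequencing depth is unknown and no interval for read counts was computed. One interval, for a ratio of numbers of called nucleosomes, treats the calls as independent counts.

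The heights showed how they had been scaled. They lay on steps of 0.25 multiplied by a factor. In replicate 1 this factor was the same for all 19 autosomes, at 1.00001 (3 months) and 0.99999 (21 months). In replicate 2 it differed between autosomes, from 0.998 to 1.005 at 3 months. The inverse factors of the 3-month and 21-month libraries of one replicate number summed to 2.00 on every autosome, so each pair had been brought to a common total. The replicate 1 lists also held unplaced sequence, and the replicate 2 lists did not. The replicate numbers were therefore treated as processing batches, and differences within each pair are given beside the pooled ones. The labels do not state that a replicate number marks a shared day or litter. Over 2103392 windows, the deviations from the age means of the 2 libraries numbered 1 correlated at 0.20.

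Values per library were computed in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, on the autosomes, X and Y, or on autosomes alone for distances and sharing. Spacing was the median distance between neighbouring centres, for distances up to 1000 bp, and a gap was a distance over 500 bp. The repeat length was the slope through the peaks 2 to 5 of the histogram of all distances between centres. A position was shared when the other library had a centre within 20 bp, with a comparison value taken after a shift of 1000 bp. That shift lies near peak 5 of the histogram (981 to 989 bp). The shifted share can therefore include the regular spacing and may exceed sharing by chance. Groups were compared with an exact two-sided permutation test, which cannot give a p below 0.33 for 2 libraries against 2.

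For windows of 1000 bp on the autosomes holding at least 2 nucleosomes in every library, the mean height was divided by the library's median. The log2 of this value plus 0.1 was compared with limma 3.58.1 in R 4.3.3 (trend and robust on, Benjamini-Hochberg adjustment, threshold 0.05). On data simulated from the real windows with 200 changed per fold size, this fit recovered 0% of 1.5-fold, 30.5% of 2-fold, 93% of 3-fold and 98.5% of 4-fold changes, with 2, 6, 28 and 19 false calls. With the replicate number as a block, the shares were 2.5%, 67.5%, 99.5% and 100%, with 0, 11, 17 and 17 false calls. Both simulations drew independent normal noise at the spread that the fit itself had estimated, and the one without a block held no replicate effect. The shares and false calls therefore apply where the model of each fit holds, and may differ on the real windows. The windows named are, in each direction, the 10 with the smallest p in which both 21-month libraries lay on one side of both 3-month libraries. Windows within 5000 bp were named once.

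The gene table at hand is of GRCm38, whereas the last nucleosome on chromosome 7 lies at 152524351 and the last GRCm38 gene there ends at 145324059. Coordinates of different builds were not mixed. Promoters, start sites, the gene lists and a GC correction are therefore not analysed here, and regions are given by mm9 position alone. Tests, windows, alternatives and the naming rule were fixed before the data were examined. The search for long segments, the added alternatives and the tests of explanations were chosen after seeing the data. In that search, sums of heights in 10 kb windows were compared between 1 library and the median of the other 3, over running medians of 7 windows. A segment needed a log2 difference over 0.5 and a range of the other 3 libraries under 0.3. That range was first set at 0.25, and the wider value adds 1 segment. A height limit used for X and Y was moved from 10 to 9.9 after the counts were seen, because 10 lies on a step of the heights and falls on different sides of the limit in differently scaled libraries. Results at both limits are given.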

Results

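The data were genome-wide maps of called nucleosomes in liver from mice aged 3 and 21 months, with 2 libraries per age. The design asks how nucleosome occupancy differs between young and old liver. On autosomes, X and Y, the 3-month libraries held 8077079 (replicate 1) and 8629783 (replicate 2) nucleosomes. The 21-month libraries held 7964115 and 8622319.

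The number of called nucleosomes in young and old liver differed by less than the replicates of one age. The mean was 8353430 ± 390821 (SD, n = 2) at 3 months and 8293220 ± 465421 (SD, n = 2) at 21 months, a difference of -0.72% (exact permutation test, two-sided, p = 0.667). The difference was -1.40% within replicate 1 and -0.086% within replicate 2, while the replicate 2 libraries held 7.55% more nucleosomes than the replicate 1 libraries. Median nucleosome height was 16.6 ± 0.87 (SD, n = 2) at 3 months and 16.8 ± 1.05 (SD, n = 2) at 21 months (exact permutation p = 1.0). The height difference was 0.25 within replicate 1 and -0.0053 within replicate 2. Each pair had been brought to a common total, so these heights cannot show a difference in total occupancy between the ages. Median fuzziness, the spread of fragment positions around a nucleosome's centre, was 24.1 ± 0.87 (SD, n = 2) at 3 months and 24.1 ± 0.82 (SD, n = 2) at 21 months (exact permutation p = 1.0). Its difference changed sign between the pairs, at -0.038 and 0.040.

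The regular spacing of nucleosomes along liver chromatin differed between the ages by less than the replicate spread. The nucleosome repeat length was 197.8 ± 0.65 bp (SD, n = 2) at 3 months and 197.9 ± 0.62 bp (SD, n = 2) at 21 months (exact permutation p = 0.667). It was longer at 21 months by 0.072 bp within replicate 1 and by 0.030 bp within replicate 2, against a spread over chromosomes of 0.58 to 0.96 bp (SD) within a library. The median distance between neighbouring centres was 255 and 230 bp in the 3-month libraries and 260 and 230 bp in the 21-month libraries (exact permutation p = 1.0). Arrays were sharper in replicate 2. After the histogram was smoothed by a running mean, the peak near the 2-nucleosome distance was 1.58 and 1.49 times the following trough there, at 3 and 21 months. In replicate 1 it was 1.29 and 1.32 times the trough.

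**Figure D1:**
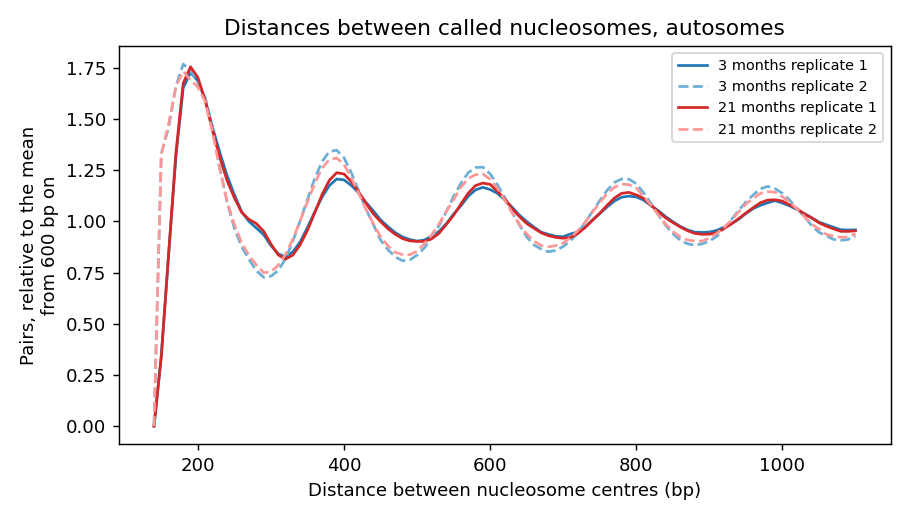
Number of nucleosome pairs (vertical axis, relative to the mean from 600 bp on) at each distance between centres (horizontal axis, bp) on autosomes, 1 line per library. From the 2-nucleosome peak on, the replicate 2 lines (dashed) have higher peaks than the replicate 1 lines at both ages. Peak-to-trough ratios, computed after smoothing and so lower than the lines show, were 1.58 (3 months) and 1.49 (21 months) against 1.29 and 1.32.

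Stretches without a called nucleosome did not become consistently more frequent with age. Gaps over 500 bp numbered 386052 ± 53060.6 (SD, n = 2) at 3 months and 396586 ± 69923.7 (SD, n = 2) at 21 months (exact permutation p = 1.0). They were 5.30% more frequent at 21 months within replicate 1 and -0.40% different within replicate 2. Some gaps were common to both libraries of one age and filled by at least 2 nucleosomes in each library of the other. There were 11572 such gaps at 21 months and 7144 at 3 months, which are 6.40% and 4.07% of the gaps common to each pair. Pairing each old library with the young library of the other number gave 10770 and 7323, with the larger number again on the side that holds 21 months replicate 1.

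Individual nucleosome positions were shared no more within an age than between ages. The 3-month libraries shared 24.5% of positions and the 21-month libraries 24.9%, compared with 17.8% and 17.7% after a shift of 1000 bp. Libraries of different age shared 30.1% in replicate 1, 44.3% in replicate 2, and 24.6% and 24.7% across replicate numbers. Same-age pairs thus shared 6.25 percentage points less than different-age pairs, but both same-age pairs cross the replicate numbers. Among pairs that cross them, sharing was 24.5% and 24.9% within an age and 24.6% and 24.7% between ages, so no age difference appeared there. The ranking that follows treats the libraries as exchangeable, which the replicate batches do not allow. Of the 3 ways to part the 4 libraries into pairs, the split by age ranked second and the split by replicate number first, with a difference of 12.5 points (exact one-sided p = 0.667 for age; 3 splits cannot give less than 0.333).

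**Figure D2:**
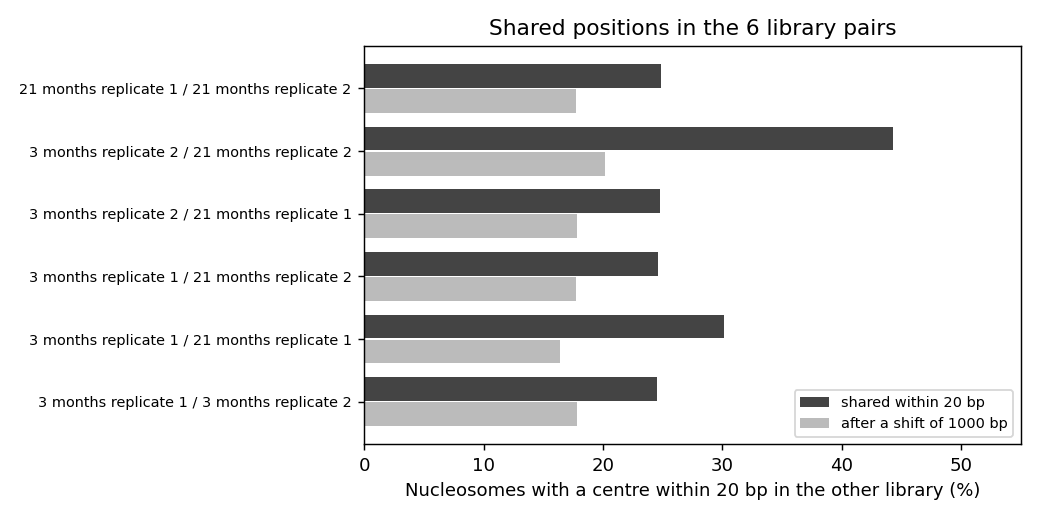
Share of nucleosomes with a centre within 20 bp in the other library (dark bars, %) and after a shift of 1000 bp (light bars) for the 6 library pairs, without error bars since each pair has 1 value. The pairs with the same replicate number stand highest, at 30.1% and 44.3%, and the other 4 lie between 24.5% and 24.9%.

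No 1 kb autosomal window was called different in nucleosome height between the ages in the main comparison fixed beforehand. Of 2103392 autosomal windows, limma called 0 at an adjusted p of 0.05, and 60933 (2.90%) had an unadjusted p under 0.05. Both 21-month values lay above both 3-month values in 13.98% of windows and below them in 15.2%, where chance gives 16.7% for each if all 4 libraries are exchangeable, which the replicate batches do not allow. For the crossed split, the shares were 13.7% and 14.8%. With the replicate number as a term for the processing batch, an alternative also fixed beforehand, limma called 57 windows, 33 higher and 24 lower at 21 months. With 4 libraries, this fit rests mostly on the spread pooled over windows, and a call does not require that both pairs agree. Most called windows moved in one direction in both pairs. The window on chromosome 3 at 151364001 was called with log2 differences of -0.16 in replicate 1 and 2.95 in replicate 2. Block fits of the same form called 11 windows for the split that crosses age and replicate number, and 25187 for the replicate number with age as the block. Without a block, the replicate number called 4251 windows and the crossed split 0. For age without a block, larger windows gave 4 calls of 462540 at 5 kb and 16 of 235743 at 10 kb. Leaving out 1 library gave 127 calls without 3 months replicate 1, 89 without 21 months replicate 1, 3 without 21 months replicate 2 and 2 without 3 months replicate 2.

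The windows named by the fixed rule did not pass in the main comparison (limma adjusted p = 0.99999 for each). The smallest p belonged to chromosome 6 from 61736001 to 61737000 (mm9), where mean height was 9.50 and 9.85 in the 3-month libraries and 29.7 and 19.5 in the 21-month libraries, a log2 difference of 1.16 (SE 0.21). On chromosome 6 from 79112001 to 79113000, heights were 6.17 and 2.75 at 3 months and 16.4 and 13.98 at 21 months (log2 difference 1.49, SE 0.28). The window on chromosome 10 from 86340001 to 86341000 had heights of 14.1 and 10.01 at 3 months and 32.4 and 22.5 at 21 months (log2 difference 1.06, SE 0.20). In the other direction, chromosome 10 from 14941001 to 14942000 had 27.6 and 23.0 at 3 months and 14.2 and 9.99 at 21 months (log2 difference -1.0005, SE 0.20). Chromosome 11 from 13786001 to 13787000 had 23.3 and 18.2 at 3 months and 10.4 and 6.99 at 21 months (log2 difference -1.14, SE 0.22). The window on chromosome 3 from 90237001 to 90238000 had 21.8 and 33.2 at 3 months and 14.7 and 6.51 at 21 months (log2 difference -1.32, SE 0.25). Its pairs were unequal, with log2 differences of -0.55 in replicate 1 and -2.10 in replicate 2.

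The other windows named as higher at 21 months start at 73281001 on chromosome 15, 116554001 on chromosome 8, 42445001 on chromosome 18, 127336001 and 55159001 on chromosome 6, 80840001 on chromosome 5 and 170483001 on chromosome 1. Those named as lower start at 35435001 on chromosome 16, 51069001 on chromosome 2, 18156001 on chromosome 17, 65381001 and 135208001 on chromosome 7, 48779001 on chromosome 6 and 74823001 on chromosome 5. The log2 differences ran from 0.90 to 1.49 in the 10 higher windows and from -0.90 to -1.32 in the 10 lower ones. With a pseudocount of 1 they shrank to 0.50 to 0.62 and -0.51 to -0.71. Of these 20 windows, 19 passed when the replicate number was in the model. That fit has the same log2 differences and uses the values by which the windows were picked, so it is no separate support. The alternative of at least 4 nucleosomes in every library holds none of the 20 and could not test them. In 17 of the 20, the mean number of called nucleosomes moved opposite to the mean height. None of the 20 passed when heights were summed in place of averaged, with or without the replicate number in the model. On sums, the log2 differences ran from 0.30 to 1.95 and from -0.12 to -1.22, and were as large as on means in 3 windows and smaller by over 1.5 times in 11. The genes at these positions are not analysed here.

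Height differences between the ages repeated only slightly from one replicate pair to the other in 1 kb windows, and their correlation was near 0 or negative in larger windows. The difference between 21 and 3 months in replicate 1 correlated with that in replicate 2 at r = 0.014 (jackknife SE 0.0008 over chromosomes) across 1 kb windows, and at -0.0058 (SE 0.0045), -0.079 (SE 0.023) and -0.12 (SE 0.095) across windows of 10, 100 and 1000 kb. In 10 kb windows with at least 30 nucleosomes in every library it was 0.0051 (SE 0.0030). The difference between replicates 2 and 1, taken at each age, correlated at 0.20, 0.37, 0.69 and 0.86. These correlations are across windows, which are not independent replicates. Among 1 kb windows that differed by over 2 SD in both pairs, 3371 moved in the same direction and 2836 in opposite directions, with the same direction more frequent on 19 of 19 chromosomes. At 10 kb the order turned, with 542 in the same and 631 in opposite directions.

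**Figure D3:**
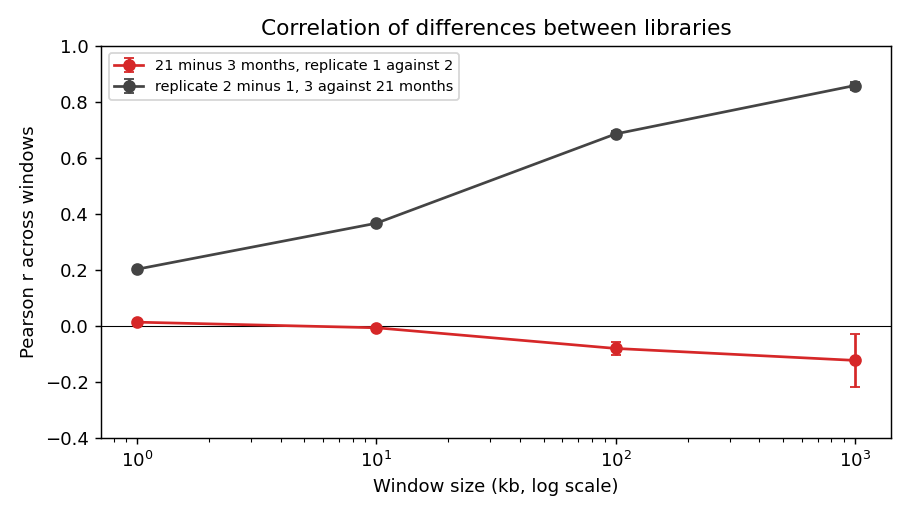
Pearson r across autosomal windows (vertical axis) by window size (horizontal axis, kb, log scale), with jackknife SE over chromosomes as error bars. Age differences of both replicate pairs (red) lie near 0 or below, from 0.014 to -0.12, and replicate differences of both ages (dark) rise from 0.20 to 0.86.

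The sex chromosomes had lower nucleosome heights than the autosomes in every library. Heights were not divided by the number of copies of a chromosome, so these values do not separate copy number from occupancy. Mean height on X, relative to the autosomal median, was 0.57 and 0.60 in the 3-month libraries and 0.57 and 0.60 in the 21-month libraries, and on Y 0.52 and 0.52 against 0.51 and 0.53. The difference on X was -0.0068 (exact permutation p = 0.667). By median height, a summary added after seeing the data, both 21-month libraries lay below both 3-month libraries, with means of 0.544 against 0.566 on X and 0.492 against 0.4996 on Y (exact permutation p = 0.333 for each, the smallest this design allows). The same order was found on 3 of the 19 autosomes, with a difference as low as -0.022 on chromosome 1 (X -0.022), and medians lie on the coarse steps of the heights. The number of called nucleosomes per Mb on X was 2238 and 2221 at 3 months and 2067 and 2277 at 21 months. Within replicate 1, the number on X changed by -7.64% from 3 to 21 months and that on Y by -15.6%, while autosomes changed by -1.34% to -0.80%. Within replicate 2, X changed by 2.53% and Y by -0.18%.

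In 3 long segments on chromosomes 14 and 19 (mm9), 1 of the 3-month libraries had lower summed nucleosome height than the other 3 libraries. On chromosome 14 from 69870001 to 70090000 this was 3 months replicate 1, by -0.86 on the log2 scale (SD 0.15 over 22 windows). Relative to the chromosome median (log2), 3 months replicate 1 stood at 0.17 there and the other libraries at 1.01 to 1.03. On chromosome 19 it was 3 months replicate 2, by -0.81 (SD 0.15 over 6 windows) from 36990001 to 37050000 and by -0.79 (SD 0.12 over 14 windows) from 37310001 to 37450000. There 3 months replicate 2 stood at -0.20 and -0.0082, against 0.57 to 0.70 and 0.75 to 0.83 in the other libraries. In all 3 segments the other libraries were thus raised above the chromosome median, and the library apart lay nearer to it. The segments were found by a search chosen after seeing the data, and no test between the ages applies to a single library.

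**Figure D4:**
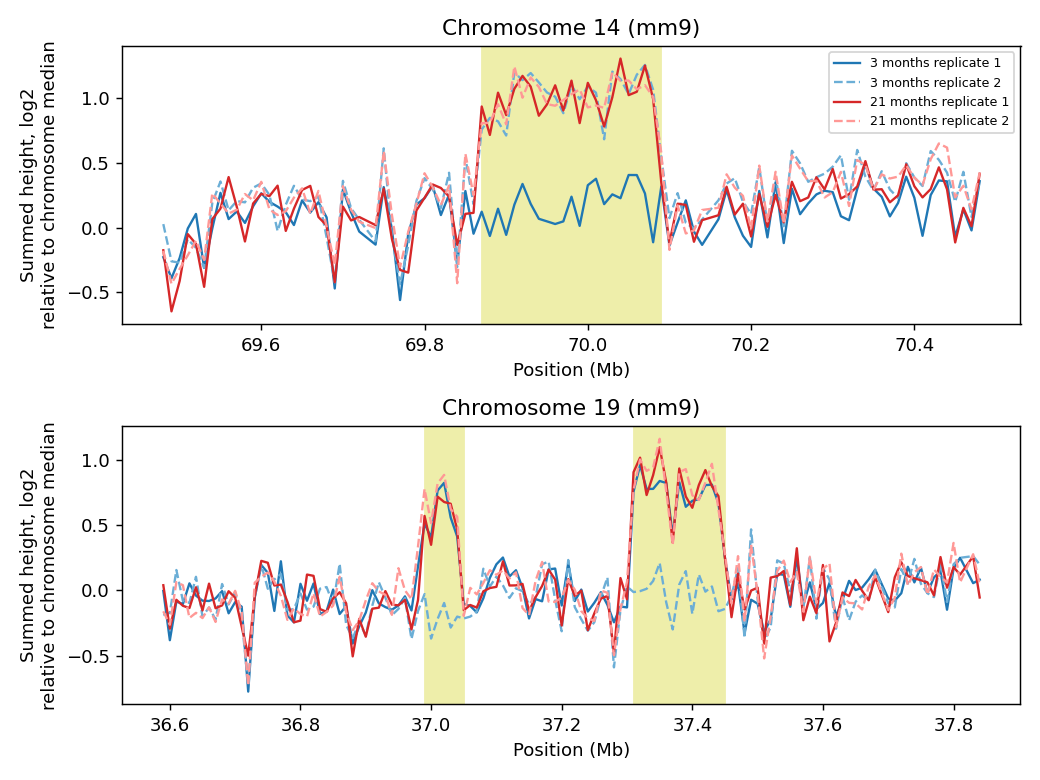
Summed nucleosome height per 10 kb window (vertical axis, log2 relative to the chromosome median) by position (horizontal axis, Mb, mm9) on chromosomes 14 and 19, 1 line per library, with the segments shaded. Within the shading 3 months replicate 1 (chromosome 14) and 3 months replicate 2 (chromosome 19) lie below the other 3 libraries, by -0.86, -0.81 and -0.79. They lie nearer the chromosome median, and the other 3 libraries lie above it.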

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

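Apart from an alternative that took median height over all chromosomes, calls outside the autosomes, X and Y were not used in any comparison. They were noted because a signal appears there. On the mitochondrial genome, which carries no nucleosomes, median height was 79.4 and 47.6 in the 3-month and 21-month libraries of replicate 1 and 7.11 and 7.68 in those of replicate 2. Unplaced sequence held 10035 nucleosomes in 3 months replicate 1 and 8952 in 21 months replicate 1.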

How the results depend on the processing

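Leaving out 1 library turned the direction of most whole-map differences, and it also left the replicate numbers unbalanced between the ages. The difference of 21 minus 3 months then ranged from -389316 to 268888 nucleosomes, from -0.62 to 0.86 in median height, from -0.62 to 0.62 in fuzziness, from -12.5 to 17.5 bp in spacing, from -38910.5 to 59976.5 gaps and from -0.023 to 0.0095 in X height. For shared positions it ranged from -9.93 to -2.52 percentage points. These ranges take in the offset between the replicate numbers. Replicate 2 against replicate 1 differed by 7.55% in the number of nucleosomes, -7.80% in median height and -20.0% in gaps. Within the pairs, the number of nucleosomes differed by -112964 (replicate 1) and -7464 (replicate 2). With only the nucleosomes at or above the median height, fuzziness (-0.0050), spacing (-2.5 bp) and gaps (-7572.5) reversed. Why these measures reversed with that filter was not tested.

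The count of 1 kb windows moved from 0 to between 2 and 127 when 1 library was left out, where the lone library of an age is assumed to vary like the other pair. It was 57 with the replicate block, 54 with the block and without the long segments, and 61 with the block and scaling by chromosome. Block fits gave 3 on summed heights, 15 in 0.5 kb, 354 in 5 kb and 198 in 10 kb windows, and 44 on sums in 10 kb windows. Without the block, alternatives fixed beforehand gave 4 calls in 5 kb windows, all lower at 21 months. In 10 kb windows they gave 16, with 4 higher and 12 lower at 21 months. Of these calls without the block, 0 lay in the long segments. Of the 198 and the 44 calls with the block in 10 kb windows, 41 and 32 lay in the long segments of the other observations. The number of nucleosomes gave 125718 with and without the block, and all 125718 had equal numbers within each age, so ties made the test void. The other alternatives run gave 0. Block fits other than the plain one, sums in 10 kb windows, scaling by chromosome and fits without the segments were added after seeing the data. The shared scaling shows that libraries of one number were processed together; the labels do not say whether they share more.

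On the number of nucleosomes, with and without the replicate block, 17 named windows reversed. The windows higher in mean height had log2 differences in number of -0.24 (chromosome 6 at 61736001 and 127336001), -0.67 (chromosome 10 at 86340001, chromosome 5 at 80840001), -0.42 (chromosome 15 at 73281001, chromosome 8 at 116554001) and -0.49 (chromosome 1 at 170483001, chromosome 6 at 55159001). Those lower in mean height had 0.67 (chromosome 10 at 14941001, chromosome 7 at 135208001), 0.24 (chromosome 11 at 13786001, chromosome 5 at 74823001), 0.42 (chromosomes 3 and 16), 0.18 (chromosome 2), 0.49 (chromosome 17) and 0.81 (chromosome 7 at 65381001). The alternatives for promoters, start sites, gene lists and GC content were not run. The unknown read depth limits every value.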

Other observations

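All tests of explanations in this part were chosen after the results were seen.

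Several stretches of chromosome had a different nucleosome height in 1 library than in the other 3. On chromosome 14 from 69870001 to 70090000 (mm9, 220 kb), the other 3 libraries stood 1.81-fold above 3 months replicate 1, in all 22 windows. On chromosome 19, 36990001 to 37050000 and 37310001 to 37450000 stood 1.75-fold and 1.74-fold above 3 months replicate 2. A weaker segment on chromosome 13 from 101050001 to 101120000, higher in 21 months replicate 2 by 0.70 on the log2 scale, appears only when the range allowed to the other 3 libraries is 0.3 or wider. Limits of 0.2 and 0.25 leave the 3 segments on chromosomes 14 and 19, and a log2 difference of 0.7 leaves 2.

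Scaling by the authors is argued against on chromosomes 14 and 19, since the sequence up to 1 Mb on both sides differed by at most 0.065 of the segment difference. An age effect on these segments is argued against because the other 3-month library differed from the 21-month libraries by at most 0.088 of it, in a search with no limit on the range of the other libraries, which found the same 4 segments. A copy number difference between the animals is a candidate explanation on chromosomes 14 and 19: mean heights differed by 1.71 to 1.73 times while the number of called nucleosomes differed by at most 1.11 times. On chromosome 13 the number differed 1.22-fold (95% counting interval 0.96 to 1.55), so there it stays open. Copy number remains a hypothesis, found and tested on the same data, and no sequence data were used here.

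The difference between the replicate numbers correlated between the ages, more closely in larger windows, up to r = 0.86 at 1 Mb. The difference itself did not grow. Its SD was 0.303 (3 months) and 0.305 (21 months) in 1 kb windows, and 0.063 and 0.046 in 1 Mb windows. The authors' scaling by chromosome in replicate 2 is argued against, since r was 0.86 (0.8553) after chromosome medians were removed. Sparsely covered sequence as the whole source is argued against at 10 kb, since r was 0.38 in 10 kb windows with at least 30 nucleosomes in every library (0.37 in all 10 kb windows). Repeated sequence stays open, since a minimum number of nucleosomes does not remove it and repeats were not marked. Differences in digestion, sequencing or caller settings between the replicate numbers stay open and untested, and no biological explanation was tested.

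X and Y held fewer called nucleosomes in 21 months replicate 1 than in its 3-month partner. A higher calling limit for low nucleosomes is argued against as the whole of it, because among heights of 9.9 or more the ratio on X was 0.951, against 0.991 to 1.002 on autosomes. That limit lies near the median height on X (9.75 in both replicate 1 libraries, 9.49 and 9.01 in replicate 2). It lies well below the medians of the whole libraries (16.0 to 17.5). A small shift in height thus moves a larger share of calls across it on X, so the comparison is not fully alike. At the limit first chosen, 10, the ratios were 0.856 on X and 0.975 to 0.987 on autosomes. There the step at 10 counted at 3 months and fell below the limit at 21 months, so these values decide nothing. An effect of age on X cannot be told apart here. In replicate 2 the number on X changed by 2.53%. The scaling factors give a ratio before scaling of 0.998 on X, within the autosomes at 0.9951 to 1.011. Neither value shows a loss on X beyond that of the autosomes. Among heights of 9.9 or more, however, the ratio was 0.992, below the autosomes at 0.997 to 1.005, with the same unlike limit. At a limit of 10 the ratio was 1.201, above their 0.957 to 1.048. There the step at 10 on X fell below the limit at 3 months only, so this value decides nothing. An effect of age on Y cannot be told apart either. In replicate 2 the number on Y changed by -0.18%, and the ratio was 1.119 at 9.9 and 1.114 at 10 (0.829 and 0.716 in replicate 1). The replicate 2 factors on Y, 0.976 (3 months) and 1.026 (21 months), put the step at 10 on different sides of both limits. These factors give a ratio before scaling of 0.951, below the autosomes at 0.9951 to 1.011, though only 64.4% and 65.5% of the Y heights lie on the inferred steps. Base composition and differences between animals also stay open, as untested.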
